A study of Mus musculus with 4 samples.

How the data were processed

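Single-cell RNA was measured in CD11b-selected cells of the mouse cortex at postnatal day 15, in 2 libraries from animals given the mCherry virus and 2 from animals given the Hevin virus. Per the labels' protocols, up to 40000 cells entered each PIPseq reaction, and actinomycin D, triptolide and anisomycin were present during tissue dissociation. The authors deposited raw UMI counts per gene and barcode, with a list of genes and a list of barcodes per library. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the gene annotation and the rule by which barcodes were called cells are not given in the sources used here. The deposited barcodes had a lowest total between 965 and 2993 UMIs that differed by library, so the depth at which barcodes were admitted was not common to the groups. Whether counting used strand is likewise not given.

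Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% of UMIs from mitochondrially encoded genes, which removed 44 and 28 barcodes of the mCherry libraries and 202 and 41 of the Hevin libraries before doublets were considered. Scrublet, as run in scanpy, called 1 barcode in each mCherry library (0.006% and 0.009%) and 230 and 265 in the Hevin libraries (1.158% and 2.026%). It did not work in the mCherry libraries, so removing its calls treated the groups unequally, and alternatives kept the calls or removed the top 5% of doublet scores in each library. Kept cells numbered 17832 and 10848 in the mCherry libraries and 19423 and 12772 in the Hevin libraries. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1, with no integration of libraries. This gave 21 clusters. A pair of mixed clusters was split again (1000 variable genes, 15 components, resolution 0.5), which gave 33 in all.

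A cluster was called by a class ("microglia-like") from markers of 14 classes. A marker counted as present at 20 CPM or more and at 40% or more of its highest level in any cluster. A class needed at least 3 and 75% of its markers, with no other class holding more markers among the cluster's top 10 genes by fold. A shallow cluster, with a median under 33% of the depth of its libraries, also needed a marker of the class among those 10. Clusters that failed stayed unnamed. Those with at least 15000 CPM of Apoe and less than 50 CPM of Sall1 were pooled as Apoe-high clusters. These bounds were set after the data had been seen, as was the choice to pool them. The cells were clustered again without 2363 genes, those with an unadjusted p below 0.05 in microglia-like cells or an adjusted p below 0.05 over all cells.

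Raw counts were summed per library over all kept cells and over each class with at least 20 cells in every library. Neutrophil-like, oligodendrocyte-like, oligodendrocyte-precursor-like, fibroblast-like and erythroid-like cells had too few. Sums were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, group as the sole term), and Benjamini-Hochberg adjusted p below 0.05 was the threshold. CPM in these comparisons are TMM-scaled, and CPM of single cell groups per library, as for Sparcl1, the sex-linked genes and the Apoe-high clusters, are plain. The difference of the Hevin effect between border-associated-macrophage-like and microglia-like cells was tested as an interaction with the library as a block. Numbers of cells per class were tested with edgeR on the kept cells of each library, with an exact two-sided permutation test of the shares beside it. The share of dividing cells was taken after thinning each cell to 1000 UMIs, which left out 335 shallower cells over all classes and libraries.

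The 31 gene lists were tested with camera from limma (correlation preset at 0.01), adjusted over the lists, with an estimated correlation and fry beside it. They covered ribosomal protein, homeostatic microglia, developmental and disease-associated microglia, interferon-response, NF-kappa-B, Toll-like receptor, phagocytosis and complement, lysosome, antigen presentation, S-phase, G2 and M phase, dissociation-induced, glycolysis, lipid handling, mitochondrially encoded, TGF-beta, extracellular matrix and synaptic and neuronal receptor genes, and the markers of 13 cell types other than microglia. Lists with fewer than 3 measured genes in a cell class were not tested there. Lists in all kept cells were added after the data had been seen. The tests, lists, markers, cell filters, cluster settings and most alternatives were chosen before the data were examined.

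Genes were named by a fixed rule: among genes past the threshold, with a mean of at least 10 CPM and groups that do not overlap, the 10 with the largest and the 10 with the smallest log2 fold change in microglia-like cells and 5 and 5 in the other fits; where fewer passed, the genes of smallest unadjusted p with at least 10 CPM, up to 5 higher and 5 lower, said to miss the threshold; the 3 members of each list with the smallest unadjusted p in microglia-like cells; Sparcl1 and the 3 highest astrocyte markers; Tlr2 and Tlr4; Xist and Ddx3y. Apoe, Ms4a7, Clec12a, Cybb, Sall1, P2ry12, Tmem119, Lyve1, F13a1, Cd163, Ccr2, Pf4, Mrc1, Tafa2, Olfml3, Cxcl10 and Isg15 were also named where the rule did not ask for them, as were Uty, further border-associated macrophage markers and the leading genes of clusters, all after their values were seen.

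Coordinates are from GENCODE vM21 on mm10, which held 32098 of the 32227 gene identifiers and all 135 named genes. Of the named genes, 25 overlap another gene on the same strand (Khdrbs3, Csmd3 and Nav3 among them) and 48 on the other strand (Gpr65, Cyp4f18, Runx3, P2ry12 and Sparcl1 among them), whose reads could not be told apart here. Genes with close copies, such as H2-K1 and H2-D1, Klra2, the Ms4a genes, Ifi204, Bcl2a1b, the hemoglobins, ribosomal protein genes, Gm36161 and Gm21188, are uncertain, since the counting may have split or dropped their reads.

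The edgeR test in 3 of the sums and camera were tried on simulated data drawn from real means and library sizes, with 50 genes changed at each size. The interaction, the endothelial-like and astrocyte-like fits, the cluster shares and the dividing share were not simulated. At changes of 1.5, 2, 4 and 8-fold, edgeR recovered 13, 24, 40 and 48 genes in the microglia-like simulation (17122 genes, 17 false calls), 21, 32, 44 and 46 over all cells (19093 genes, 21 false calls) and 19, 31, 46 and 47 in border-associated-macrophage-like cells (12335 genes, 15 false calls). Camera found the changed list in each, with 0, 1 and 1 other lists called. The simulated means came from 1 profile scaled to each library, so genes of a list had no shared drift between replicates. In the microglia-like sums the estimated correlation within lists ran from −0.32 (B cell markers) to 0.98 (erythroid markers). These runs therefore do not show how camera's preset correlation holds in the data. The test of cell numbers was tried on made-up shares, with an equal number of cells in every library and an assumed noise. It found a 4-fold change of 1 of 10 categories in 97 of 100 runs, with 11 false calls in 900 other tests. None of these settings came from the data, so the runs do not show how the test performs on these libraries.

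Alternatives were DESeq2's size factors or total counts in place of TMM, DESeq2's Wald test, a robust fit, no filter on low counts or a minimum of 10 CPM, the replicate number as a block, each library left out in turn, no cell filter or a stricter one (1000 UMIs, 500 genes, 5% mitochondrial), doublets kept, resolution 0.5, a class per cell, thinned cells, and microglia-like cells without cycling clusters or without ribosomal and mitochondrial genes. A minimum of 3000 UMIs, the top 5% of doublet scores removed, the fits and shares with or without the Apoe-high clusters, the second clustering and all alternatives for endothelial-like and astrocyte-like cells were added after the data had been seen. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9. Exact binomial intervals are at 95% and cover counting error only.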

Results

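The series asked how CD11b-positive cells of the developing mouse cortex differ when astrocytes are made to overexpress Hevin, a secreted matricellular protein encoded by Sparcl1 that promotes the formation of excitatory synapses. Newborn wild-type mice had been injected in the cortex with adeno-associated virus carrying either Hevin or mCherry, a fluorescent protein that served as the control, each driven by GfaABC1D, a promoter active in astrocytes. On postnatal day 15 the cortices were dissociated in the presence of inhibitors of transcription and translation, and cells bearing CD11b (an integrin of microglia and other myeloid cells) were pulled out on magnetic columns. Single-cell RNA libraries were made with PIPseq, which captures cells in templated emulsions and counts molecules by unique molecular identifiers (UMIs). There were 2 libraries per group. The mCherry libraries held 67832685 UMIs in 17877 barcodes (replicate 1) and 49781430 UMIs in 10877 barcodes (replicate 2). The Hevin libraries held 55629684 UMIs in 19855 barcodes (replicate 1) and 52707417 UMIs in 13077 barcodes (replicate 2). The deposited barcodes began at different depths, with a lowest total of 2038 and 2993 UMIs in the mCherry libraries and of 965 and 2178 UMIs in the Hevin libraries. Median UMIs per barcode were 3349 and 4037 in the mCherry libraries and 2317 and 3490 in the Hevin libraries. After filtering, 60875 of 61686 barcodes remained. Replicates of a group differed by far more than counting noise, with a chi-square per gene of 28.4 between the mCherry libraries and of 34.9 between the Hevin libraries. The labels do not say how many animals entered a library. Except for camera's, the p-values below therefore measure only the spread between these samples, which may be technical. Those of camera at its preset correlation compare a list with the other genes and rest largely on the spread between genes. Unless stated otherwise, shares are means ± SD and log2 fold changes are Hevin minus mCherry ± SE, with n = 2 libraries per group.

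Sparcl1 (chromosome 5, 104079111 to 104113733, minus strand, mm10), the overexpressed gene, was not detectably higher in the Hevin libraries. Over all kept cells it stood at 123 and 91.4 CPM (counts scaled to a common library total) in the mCherry libraries and at 87.4 and 79.6 CPM in the Hevin libraries (log2 fold change −0.24 ± 0.14, edgeR adjusted p = 0.351). Without mCherry replicate 2 it was lower (−0.43, edgeR adjusted p = 0.0381). Few astrocyte-like cells passed the CD11b selection, 74 and 27 in the mCherry libraries and 62 and 22 in the Hevin libraries. In them Sparcl1 stood at 5300 and 6588 CPM against 5182 and 9560 CPM (log2 fold change 0.32 ± 0.30, edgeR adjusted p = 0.995). Without Hevin replicate 2 the difference was −0.21. In microglia-like cells, which do not make Sparcl1 in quantity, it stood at 47.7 and 16.3 CPM against 38.3 and 19.4 CPM (log2 fold change −0.11 ± 0.51, edgeR adjusted p = 0.993). It became 0.86 without mCherry replicate 1 and 0.32 without Hevin replicate 2. The sources do not say whether the transcript of the virus is counted as Sparcl1, and the CD11b selection leaves few of the cells meant to carry it.

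The libraries differed in sex. Xist, the RNA of the inactive X chromosome, stood at 539 and 1046 CPM in the mCherry libraries and at 1.21 and 1208 CPM in the Hevin libraries. The Y-linked gene Ddx3y stood at 82.2 and 42.5 CPM in the mCherry libraries and at 130 and 54.8 CPM in the Hevin libraries, and Uty, also Y-linked, at 22.9 and 0.846 CPM against 43.0 and 1.08 CPM. Male cells therefore made up Hevin replicate 1 and part of mCherry replicate 1. Ddx3y still stood at 42.5 and 54.8 CPM where Uty was at 0.846 and 1.08 CPM. Its level therefore does not measure the share of male cells, and the reason was not tested. Neither Xist (log2 fold change −0.29, edgeR adjusted p = 0.952) nor Ddx3y (log2 fold change 0.69, edgeR adjusted p = 0.407) passed the test between the groups over all kept cells.

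The makeup of the CD11b-selected cells, taken by clusters, differed between the groups. Microglia-like cells, named by markers such as P2ry12 and Tmem119, were 87.5% ± 0.0286 of the kept cells in the mCherry libraries and 42.1% ± 7.42 in the Hevin libraries, 2.08-fold lower (log2 fold change −1.05 ± 0.20, edgeR test on numbers of cells, adjusted p = 0.032). A set of clusters that could not be named from the fixed markers, called Apoe-high here, held 51.7% and 42.9% of the cells in the Hevin libraries (10050 and 5483 cells) and 0.247% and 0.221% in the mCherry libraries (44 and 24 cells). Its share was 201-fold higher in the Hevin libraries (log2 fold change 7.65 ± 0.25, edgeR test on numbers of cells, adjusted p = 8.2e-05). These clusters were found with genes that themselves differed between the groups, so the cells were clustered again without 2363 genes, those with an unadjusted p below 0.05 in microglia-like cells or an adjusted p below 0.05 over all cells. A set picked there by Apoe alone, which held 79.8% of the first set, had shares of 5.64% and 2.73% in the mCherry libraries and of 53.0% and 39.5% in the Hevin libraries (log2 fold change 3.46 ± 0.45, edgeR adjusted p = 0.0029). Apoe and Sall1 themselves differed between the groups, so a set picked by them is no independent check of the share. With the bound on Sall1 as well, the set held 24.9% of the first one and its shares were 1.42% and 1.00% against 12.9% and 14.0% (edgeR adjusted p = 1.8e-06).

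**Figure D1:**
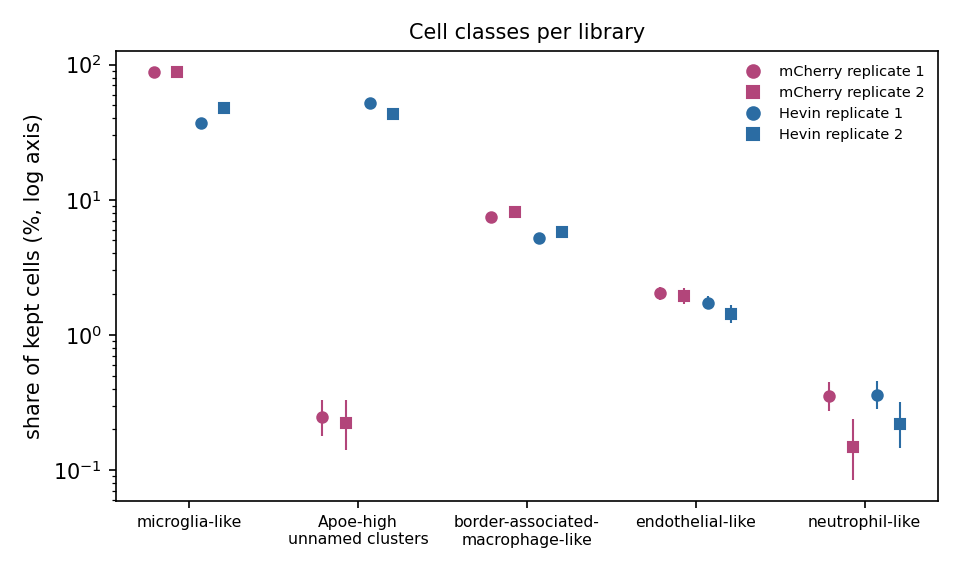
Share of kept cells, in percent on a log axis, for 5 groups of cells in each of the 4 libraries, with 95% exact binomial intervals that cover counting error only. The Apoe-high clusters sit at 0.247% and 0.221% in the mCherry libraries and at 51.7% and 42.9% in the Hevin libraries, while the microglia-like share is 87.5% in both mCherry libraries and 36.9% and 47.4% in the Hevin libraries.

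A share falls where another rises. Outside the Apoe-high clusters microglia-like cells were 87.7% of the cells in both mCherry libraries and 76.5% and 83.0% in the Hevin libraries (log2 fold change −0.14 ± 0.18, edgeR adjusted p = 0.491). The call on the microglia-like share over all kept cells did not outlast the removal of a control library (adjusted p = 0.0925 without mCherry replicate 1 and 0.0614 without mCherry replicate 2, edgeR) or a minimum of 3000 UMIs per cell (adjusted p = 0.0752). Its log2 fold change was −1.05 without either mCherry library and −1.31 with 3000 UMIs, with a larger SE of 0.38, 0.37 and 0.39. When each cell took the class of its highest marker score, which places the Apoe-high cells in a class as well, the log2 fold change was 0.0059. An exact two-sided permutation test of the shares gave p = 0.333 for the microglia-like and the Apoe-high share, the smallest value that 2 against 2 libraries allow.

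The levels of microglial and macrophage transcripts in the Apoe-high cells are given here as plain CPM in Hevin replicates 1 and 2. Apoe (chromosome 7, 19696109 to 19699188, minus strand), the lipid carrier apolipoprotein E, stood at 34547 and 36138 CPM, against 4968 and 3433 CPM in microglia-like cells. Ms4a7, a membrane protein of macrophages of the brain borders, stood at 1060 and 1208 CPM, against 101.7 and 59.8 CPM in microglia-like cells. The microglial genes P2ry12 (962.5 and 978 CPM) and Tmem119 (663 and 697 CPM) were present at lower levels than in microglia-like cells, where P2ry12 stood at 4019 and 4597 CPM. In endothelial-like cells P2ry12 stood at 422 and 351 CPM and Tmem119 at 188 and 158 CPM. P2ry12 was nearer to the Apoe-high level in other classes. It stood at 663 and 591 CPM in border-associated-macrophage-like cells and at 491 and 878 CPM in the 70 and 28 neutrophil-like cells. Sall1 (chromosome 8, 89027235 to 89044162, minus strand), a zinc-finger transcription factor of microglia whose low level was part of the rule for the set, stood at 23.2 and 22.2 CPM, against 221.5 and 289 CPM in microglia-like cells and 18.6 and 21.6 CPM in endothelial-like cells. Lyve1, F13a1 and Cd163, which mark border-associated macrophages, were low, with Lyve1 at 15.8 and 9.22 CPM against 1465 and 1676 CPM in border-associated-macrophage-like cells. Ccr2, the chemokine receptor of recently recruited monocytes, stood at 5.19 and 6.33 CPM, against 913.5 and 886.5 CPM in unnamed cluster 18, whose leading genes included H2-Eb1, H2-Aa, Cd74 and Ccr2. The Apoe-high set comprised cluster 9 (12984 cells), cluster 10 (433 cells, led by the interferon-induced genes Cxcl10, Ifit3 and Isg15), cluster 15 (1601 shallow cells with a median of 1451 UMIs), cluster 16 (309 cells, led by Spp1, Atf3 and Gpnmb) and a pair of dividing clusters of 153 and 121 cells.

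**Figure D2:**
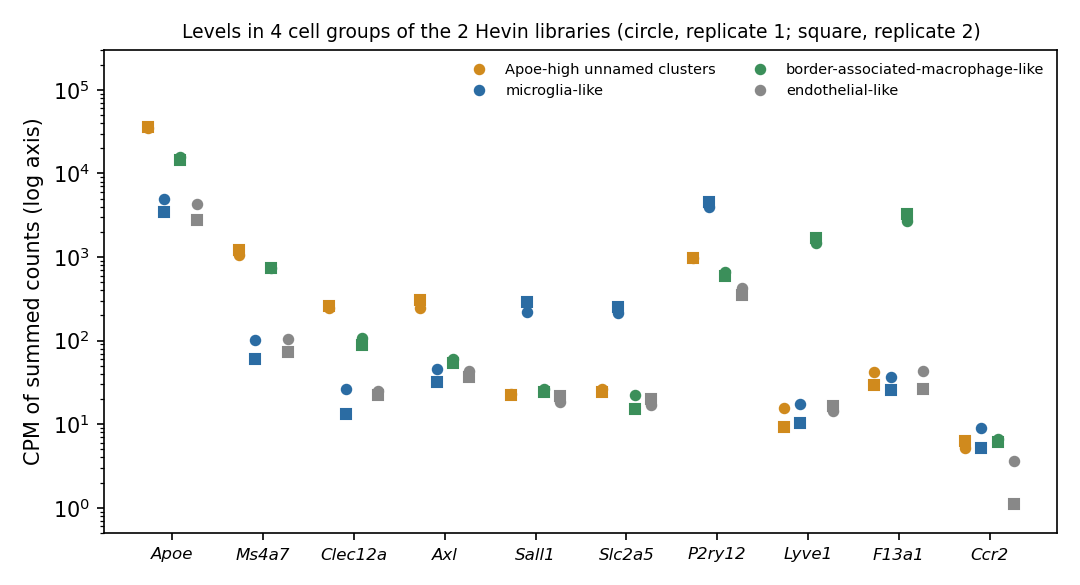
Level of 10 genes, in CPM on a log axis, in 4 groups of cells of the 2 Hevin libraries, each point being one library. Apoe stands at 34547 and 36138 CPM in the Apoe-high clusters, which have Sall1 at 23.2 and 22.2 CPM against 221.5 and 289 CPM in microglia-like cells, and Lyve1 at 15.8 and 9.22 CPM against 1465 and 1676 CPM in border-associated-macrophage-like cells.

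No other class passed the test. Border-associated-macrophage-like cells were 7.39% and 8.18% of the mCherry libraries and 5.18% and 5.79% of the Hevin libraries (log2 fold change −0.51 ± 0.17, edgeR adjusted p = 0.106). Outside the Apoe-high clusters they were 7.40% and 8.19% against 10.7% and 10.1% (log2 fold change 0.42, edgeR adjusted p = 0.182). Of all kept cells endothelial-like cells were 2.02% and 1.95% against 1.74% and 1.43% (edgeR adjusted p = 0.285). Erythroid-like cells numbered 22 and 2 in the mCherry libraries and 1 and 0 in the Hevin libraries (edgeR adjusted p = 0.106). Their share passed without mCherry replicate 2 (edgeR adjusted p = 0.0032) and under the stricter cell filter (0.0129), and that of border-associated-macrophage-like cells at resolution 0.5 (0.0406). A count of 0 of 12772 cells allows a share of up to 0.0289% by the exact interval. The log2 fold change was 0.18 for neutrophil-like, −0.43 for astrocyte-like, −0.07 for oligodendrocyte-like, −0.00042 for oligodendrocyte-precursor-like and 0.81 for fibroblast-like cells, each with fewer than 75 cells in every library. The magnetic selection sets part of each of these shares, and the remaining unnamed clusters held 1.76% and 1.49% of the mCherry libraries and 3.50% and 1.92% of the Hevin libraries.

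Summed over all kept cells, a measure that needs no cell classes and that includes any change in makeup, 2110 of 19093 genes passed the threshold. Of these, 1308 were higher and 802 lower in the Hevin libraries. Apoe rose from 2596 ± 137 to 21062 ± 2830 TMM-scaled CPM (log2 fold change 3.02 ± 0.13, edgeR adjusted p = 8.5e-05). Axl (chromosome 7, 25757273 to 25788705, minus strand), a receptor tyrosine kinase that binds ligands on dying cells, rose from 13.6 to 166 TMM-scaled CPM (log2 fold change 3.61 ± 0.08, edgeR adjusted p = 1.5e-05). The transcription factor Runx3 (chromosome 4, 135120652 to 135177990, plus strand) rose by 5.02 ± 0.23 on the log2 scale and the proton-sensing receptor Gpr65 (chromosome 12, 98268635 to 98276644, plus strand) by 4.49 ± 0.14. The cytochrome P450 Cyp4f18 (chromosome 8, 71988482 to 72009626, minus strand) rose by 4.31 ± 0.13, the Ly49-family receptor Klra2 by 3.95 ± 0.17 and Apoc2, a cofactor of lipoprotein lipase, by 3.89 ± 0.22. All 5 had an edgeR adjusted p of 0.00019 or less. Gpr65 went from 13 to 291 TMM-scaled CPM. Among genes past the threshold with a mean of at least 10 CPM, the largest falls were in the RNA-binding protein gene Khdrbs3 (chromosome 15, 68928420 to 69101211, plus strand; log2 fold change −2.09 ± 0.15, adjusted p = 0.00055, edgeR), the smooth muscle actin gene Acta2 (−1.94 ± 0.33), Myo18b (−1.85 ± 0.20), Csmd3 (−1.83 ± 0.17) and Sdk1 (−1.55 ± 0.18). Acta2 lost its call under a stricter cell filter (adjusted p = 0.0543).

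Most of the microglial identity genes were lower over all cells. Of 18 homeostatic microglia genes, 0 were higher, 13 were lower and 5 were not called, and 15 were lower when adjusted over the list alone (median log2 fold change −0.66, camera adjusted p = 1.6e-09, adjusted p = 0.657 with an estimated correlation). Sall1 fell by 1.15 on the log2 scale, the fructose transporter Slc2a5 by 1.32, the ADP receptor P2ry12 by 0.98, the P-selectin ligand Selplg by 1.09 and Tmem119 by 0.69. P2ry12 went from 4441 to 2254 TMM-scaled CPM. Olfml3 fell by 0.53, a call lost without mCherry replicate 1 (edgeR adjusted p = 0.104) or mCherry replicate 2 (0.0878).

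Interferon-response genes rose almost as a block, with 19 of 20 higher, 0 lower and 20 higher when adjusted over the list alone (median log2 fold change 1.12, camera adjusted p = 3.4e-17, adjusted p = 0.334 with an estimated correlation). The antiviral tether Bst2 rose by 2.35 ± 0.13, the DNA sensor Ifi204 by 2.01 ± 0.07 and the ubiquitin-like modifier Isg15 by 0.85 on the log2 scale (edgeR adjusted p = 0.00019, 4.0e-05 and 0.0019). Of 18 antigen presentation genes 11 were higher, 0 lower and 7 not called, and 12 were higher when adjusted over the list alone (median log2 fold change 0.44, camera adjusted p = 2.0e-06, adjusted p = 0.657 with an estimated correlation). Among them the class I genes H2-K1 and H2-D1 rose by 1.19 and 0.91, and H2-DMa, which loads peptides on class II molecules, by 1.01. Ribosomal protein genes were higher in 67 of 91, lower in 1 and not called in 23, and 77 were higher and 2 lower when adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 4.8e-19, adjusted p = 0.657 with an estimated correlation). Rps28 rose by 0.68, a call lost without mCherry replicate 1 (edgeR adjusted p = 0.0646).

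Some genes of cell division were higher. Of 22 genes of the G2 and M phases, 9 were higher and 0 lower, and 14 were higher when adjusted over the list alone (median log2 fold change 0.53, camera adjusted p = 3.7e-08, adjusted p = 0.657 with an estimated correlation). Birc5, which acts at the mitotic spindle, rose by 0.79 and the kinesin gene Kif23 by 0.73, the second without a call when mCherry replicate 2 was left out (edgeR adjusted p = 0.12). Of 18 S-phase genes 1 was higher, Dut (0.77), and 5 when adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.657 with an estimated correlation). That call was lost among genes of at least 10 CPM (adjusted p = 0.446).

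The Toll-like receptor list, which bears on innate sensing, was mixed. Tlr2 (chromosome 3, 83836272 to 83841767, minus strand), a receptor for bacterial lipopeptides, rose by 1.32 ± 0.08 on the log2 scale, from 47.5 to 119 TMM-scaled CPM (edgeR adjusted p = 0.00025), and Tlr8, an endosomal RNA sensor, by 2.43. Tlr4 (chromosome 4, 66827584 to 66930284, plus strand), the lipopolysaccharide receptor, stood at 71.6 and 76.5 TMM-scaled CPM (log2 fold change 0.09 ± 0.09, edgeR adjusted p = 0.610), and at −0.02 when scaled by total counts only. Of the 23 genes 6 were higher, 0 lower and 17 not called, and 7 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0416, adjusted p = 0.675 with an estimated correlation). The list's call was lost without mCherry replicate 1 (adjusted p = 0.237) or Hevin replicate 2 (0.247), among genes of at least 10 CPM (0.197), with 3000 UMIs per cell (0.107) and with total counts only (0.0511).

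Other lists held members that went both ways. Of 20 developmental and disease-associated microglia genes, 8 were higher, among them Apoe, Axl and the growth factor gene Igf1 (0.75), and 3 lower. The list missed the threshold by camera (adjusted p = 0.0624, and 0.657 with an estimated correlation) and passed by fry (adjusted p = 0.0089). Of 21 genes of NF-kappa-B signalling and inflammatory cytokines, 8 were higher, among them Nfkbia (0.95 ± 0.09), the inhibitor and target of the pathway, and 1 lower (camera adjusted p = 0.0532). Of 25 phagocytosis and complement genes, 3 were higher, Axl, complement C3 (2.00 ± 0.16) and its receptor C3ar1 (1.15), and 2 lower (camera adjusted p = 0.598, with a median of −0.14, a mean of 0.13 and a downward test). Lysosome (24 genes, 4 higher and 2 lower, adjusted p = 0.598), lipid handling (20, 5 and 3, adjusted p = 0.202) and glycolysis (19, 1 and 2, adjusted p = 0.494) did not pass camera. Nor did TGF-beta signalling (18, 2 and 2, adjusted p = 0.459), extracellular matrix (20, 3 and 1, adjusted p = 0.946), receptors for synaptic and neuronal signals (19, 3 and 3, adjusted p = 0.195) or dissociation-induced genes (20, 2 and 1, adjusted p = 0.297). Within them Ctsh rose by 0.80, the lipid droplet gene Plin2 by 0.84, the membrane metalloproteinase gene Mmp14 by 2.44, the adhesion receptor gene Cd44 by 1.25 and the ATP-gated channel gene P2rx4 by 0.98, while Smad3 fell by 0.57. The 13 mitochondrially encoded genes had 0 called members and a median of 0.23 (camera adjusted p = 0.0153, adjusted p = 0.712 with an estimated correlation), without a call when mCherry replicate 2 (0.157) or Hevin replicate 1 (0.173) was left out.

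Of the 13 lists of markers of other cell types, 3 passed camera. Of 7 endothelial markers 3 were lower and 7 when adjusted over the list alone (median log2 fold change −0.33, camera adjusted p = 0.0015, adjusted p = 0.657 with an estimated correlation, lost with 3000 UMIs per cell at 0.25). Of 6 erythroid markers 1 was lower and 5 when adjusted over the list alone (median −4.70, camera adjusted p = 0.0021, adjusted p = 0.657 with an estimated correlation). Of 7 neutrophil markers 1 was lower, Ngp (−0.85) (camera adjusted p = 0.0072, adjusted p = 0.657 with an estimated correlation), a list call lost without Hevin replicate 2 (0.128) and among genes of at least 10 CPM (0.197). The border-associated macrophage markers had 4 of 9 higher, Pf4 (1.59), Mrc1 (0.75) and Ms4a7 among them (camera adjusted p = 0.202). Monocyte markers (1 of 7 higher, Ms4a4c, and 1 lower, Plac8, adjusted p = 0.713), T or NK cell (0 of 6 called, 0.601), and B cell markers (1 of 5 higher, 0.494) did not pass camera. The same held for astrocyte (1 of 8 lower, Slc1a3, 0.497), oligodendrocyte (0 of 8, 0.124), oligodendrocyte precursor (0 of 7, 0.937), neuron (1 of 8 lower, 0.394), mural (1 of 6 lower, Tagln, 0.320) and fibroblast markers (0 of 5, 0.892). Slc1a3 (edgeR adjusted p = 0.0543) and Tagln (0.0926) lost their calls under the stricter cell filter.

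These sums include the Apoe-high clusters, and whether those are another cell type or a state of microglia stays open. Without the Apoe-high clusters 154 genes passed, 135 higher and 19 lower, of which 131 were among the 2110. That set was picked by Apoe and Sall1, which differed between the groups. The drop therefore does not separate a change in makeup from a change of state. The split between higher and lower calls depended on scaling: with total counts only, which moved the median of all genes to −0.114 on the log2 scale, 949 genes were higher and 1483 lower. With 3000 UMIs per cell 1314 genes passed.

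Within microglia-like cells 0 of 17122 genes passed edgeR's threshold, with 1068 at an unadjusted p below 0.05. With the replicate number as a block, which nothing in the labels ties to a batch, 646 genes passed, 428 higher and 218 lower. The values do tie the numbers together. Replicate 1 of both groups held male cells, and deviations of libraries with the same number from their group means correlated at 0.612. The count of 0 therefore depends on how this shared spread is treated. DESeq2 called 175 genes, 136 higher and 39 lower, and leaving out 1 library gave between 10 and 116 genes. Gpr65 (log2 fold change 2.78 ± 0.22, adjusted p = 0.0588, edgeR), Axl (2.05 ± 0.17, 0.0588), Arhgap15 (1.78 ± 0.15, 0.0588), Cd52 (0.80, 0.0611) and the interferon-induced gene Ifi27l2a (0.83 ± 0.08, 0.0611) were higher in both Hevin libraries than in either mCherry library and missed the threshold. Khdrbs3 (−1.25 ± 0.11, 0.0588), Lrba (−0.57, 0.0724), Klhdc8b (−0.61, 0.106), Trp53i11 (−0.87, 0.111) and Csmd3 (−1.02 ± 0.14, 0.113) were lower and missed it as well. Apoe had a log2 fold change of 1.54 ± 0.18 (edgeR adjusted p = 0.0802), Tlr2 of 0.39 ± 0.09 (0.355) and Tlr4 of 0.07 ± 0.10 (0.984). The microglial identity genes differed little, with Sall1 at −0.24 (edgeR adjusted p = 0.929), P2ry12 at −0.27 (0.730) and Slc2a5 at −0.42 (0.429). They are among the markers that named the class, so clusters low in several of these markers were left out beforehand. Small differences were thus partly set by the naming.

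As groups, 10 of the fixed lists passed camera in microglia-like cells, each with 0 members called on its own. With an estimated correlation and by fry, 0 lists passed. The homeostatic microglia list holds markers that named the class, so its small median was partly set beforehand. Interferon-response genes had a median log2 fold change of 0.61, and 15 of 20 were higher when adjusted over the list alone (camera adjusted p = 2.9e-18, adjusted p = 0.765 with an estimated correlation), with Ifi204 at 1.40 ± 0.13 and Bst2 at 0.81. Ribosomal protein genes had a median of 0.26, and 52 of 90 were higher when adjusted over the list alone (camera adjusted p = 1.1e-21, adjusted p = 0.879 with an estimated correlation). Homeostatic microglia genes had a median of −0.19, 0 of 18 called over the list alone (camera adjusted p = 0.00010, adjusted p = 0.879 with an estimated correlation, lost without Hevin replicate 1 at 0.115). Antigen presentation genes had a median of 0.19, 4 of 18 higher over the list alone (camera adjusted p = 0.0029, adjusted p = 0.879 with an estimated correlation, lost without Hevin replicate 1 at 0.0667). Developmental and disease-associated genes had a median of 0.13, 5 higher and 1 lower of 20 when adjusted over the list alone (camera adjusted p = 0.0200, adjusted p = 0.879 with an estimated correlation, lost without mCherry replicate 2 at 0.0949 and Hevin replicate 1 at 0.0905). NF-kappa-B genes (camera adjusted p = 0.0251, adjusted p = 0.879 with an estimated correlation) lost their call without mCherry replicate 1 (0.466), Hevin replicate 1 (0.0838) or Hevin replicate 2 (0.0770), among genes of at least 10 CPM (0.139) and with 3000 UMIs per cell (0.192). The mitochondrially encoded genes (median 0.31, camera adjusted p = 2.5e-05, adjusted p = 0.879 with an estimated correlation) lost it without Hevin replicate 1 (0.0559). Genes of the G2 and M phases (median 0.36, camera adjusted p = 0.0029, adjusted p = 0.879 with an estimated correlation) lost it without Hevin replicate 1 (0.945) and among genes of at least 10 CPM (0.0684). S-phase genes (camera adjusted p = 0.00050, adjusted p = 0.765 with an estimated correlation) lost it among genes of at least 10 CPM (0.527). Erythroid markers were lower (median −5.04, 4 of 4 over the list alone, camera adjusted p = 0.0029, adjusted p = 0.879 with an estimated correlation, lost without Hevin replicate 2 at 0.0717).

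The other lists did not pass camera in microglia-like cells. Adjusted p-values were 0.135 for Toll-like receptor signalling, 0.271 for phagocytosis and complement, 0.604 for lysosome, 0.343 for dissociation-induced genes, 0.627 for glycolysis, 0.598 for lipid handling, 0.301 for TGF-beta signalling, 0.788 for extracellular matrix and 0.301 for receptors of synaptic and neuronal signals. They were 0.135 for border-associated macrophage, 0.886 for monocyte, 0.0727 for neutrophil, 0.915 for B cell, 0.914 for astrocyte, 0.598 for oligodendrocyte, 0.784 for oligodendrocyte precursor, 0.604 for neuron, 0.322 for endothelial, 0.643 for mural and 0.643 for fibroblast markers. The median was below 0 and the test upward for phagocytosis (−0.0075), extracellular matrix (−0.11) and astrocyte markers (−0.02).

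Several measured facts stand beside these values. With an unadjusted p below 0.05 and a mean of at least 10 CPM, 21 genes more than doubled in microglia-like cells. Their rise in CPM in endothelial-like cells of the same libraries was 1.01 times that in microglia-like cells (median ratio, quartiles 0.876 and 1.19). In UMIs per cell, which the depth of the classes enters, the median ratio was 2.25 (quartiles 1.82 and 2.91). The largest cluster of microglia-like cells differed between the libraries of a group. Cluster 1 held 58.2% of them in mCherry replicate 1, clusters 2 and 3 held 40.6% and 43.3% in mCherry replicate 2, cluster 5 held 69.4% in Hevin replicate 1 and cluster 3 held 46.4% in Hevin replicate 2. None of the 10 microglia-like clusters passed the test of shares between groups (edgeR, smallest adjusted p = 0.447). Cluster 5 alone had an unadjusted p below 0.05 (edgeR p = 0.0447, exact permutation p = 0.333). Adding the Apoe-high clusters to the microglia-like cells gave 2280 genes, and giving each cell the class of its highest marker score gave 2372.

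**Figure D3:**
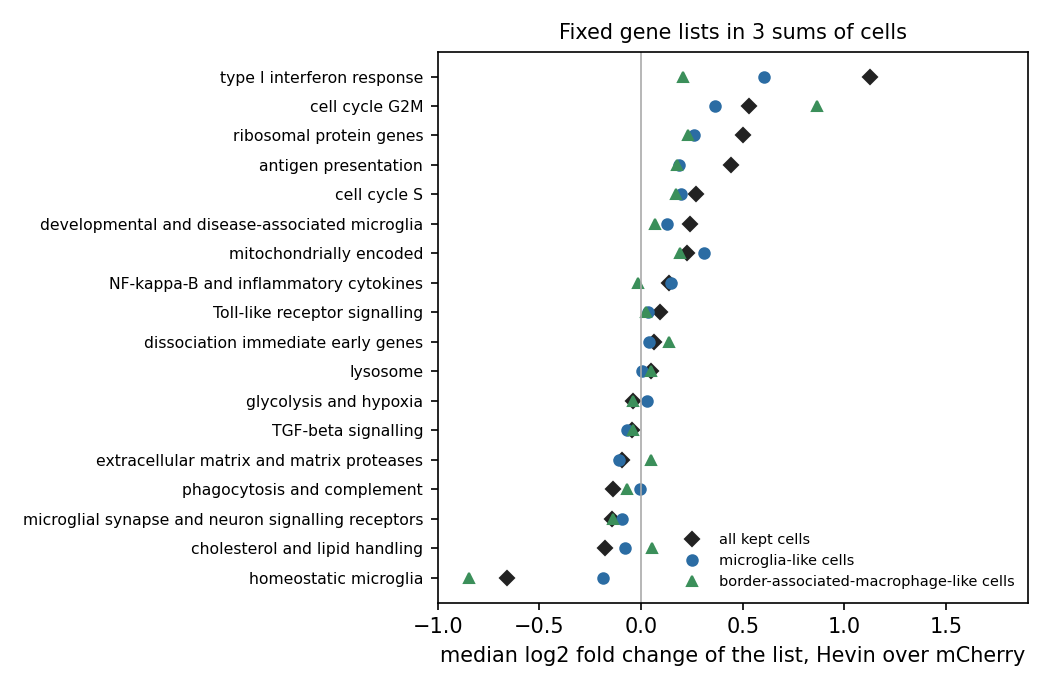
Median log2 fold change (Hevin minus mCherry) of 18 fixed gene lists in all kept cells, microglia-like cells and border-associated-macrophage-like cells, one point per list and cell group. The interferon-response list stands at 1.12, 0.61 and 0.21, and the homeostatic microglia list at −0.66, −0.19 and −0.85.

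In border-associated-macrophage-like cells, 138 of 12335 genes passed edgeR's threshold, 30 higher and 108 lower. With each cell in the class of its highest marker score 108 genes passed, 67 higher and 41 lower, of which 58 were among the 138. Among those with a mean of at least 10 CPM, the largest falls were in the zinc-finger gene Sall3 (log2 fold change −1.96 ± 0.36, adjusted p = 0.0332, edgeR), the neuron navigator genes Nav3 (−1.94 ± 0.13, 0.00016) and Nav2 (−1.90 ± 0.12, 0.00016), Slc2a5 (−1.85 ± 0.17, 0.0011) and Tmem44 (−1.77 ± 0.22, 0.0036). Slc2a5 went from 68.9 to 19.3 TMM-scaled CPM. Homeostatic microglia genes were lower in 14 of 18 and in 15 when adjusted over the list alone (median log2 fold change −0.85, camera adjusted p = 2.6e-17, adjusted p = 0.682 with an estimated correlation), with Sall1 at −1.41, Tmem119 at −1.16 and P2ry12 at −0.99. The same list had a median of −0.76 in endothelial-like cells. Axl was higher (1.56 ± 0.15, edgeR adjusted p = 0.0012, from 19.9 to 58.6 TMM-scaled CPM), as were Gm36161 (1.80 ± 0.20), Gm21188 (1.67 ± 0.17) and the mitotic genes Ube2c (1.80 ± 0.36, edgeR adjusted p = 0.0441) and Kif23 (1.33 ± 0.21, 0.0186). Apoe (0.22, 0.402), Ms4a7 (0.09, 0.856), Tlr2 (0.30, 0.343) and Tlr4 (0.07, 0.906) did not pass.

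Genes of the G2 and M phases were higher as a group in these cells, 2 of 21 on their own and 8 when adjusted over the list alone (median 0.87, camera adjusted p = 1.4e-13, adjusted p = 0.682 with an estimated correlation). The other lists that passed camera had 0 members called over all genes except the synaptic and neuronal receptor list. They were ribosomal protein genes (median 0.23, adjusted p = 5.2e-15), erythroid markers (−5.07, 0.00032), interferon-response genes (0.21, 0.0039), antigen presentation (0.17, 0.0053), fibroblast markers (0.36, 0.0089), mitochondrially encoded genes (0.19, 0.0098) and the synaptic and neuronal receptors, with 2 of 18 lower (−0.14, 0.0486). Each had an adjusted p = 0.682 with an estimated correlation, except the mitochondrially encoded genes at adjusted p = 0.691 with an estimated correlation. Calls were lost without Hevin replicate 2 for interferon-response genes (0.278), without Hevin replicate 1 for antigen presentation and fibroblast markers (0.0594 for both), and without mCherry replicate 2 (0.235) or Hevin replicate 1 (0.584) for mitochondrially encoded genes. The synaptic and neuronal receptors lost theirs without mCherry replicate 2 (0.258), Hevin replicate 1 (0.151) or Hevin replicate 2 (0.165). The number of genes was 71 without mCherry replicate 1 and 235 without Hevin replicate 1, 36 after removal of the top 5% of doublet scores and 86 by DESeq2. Ube2c lost its call without mCherry replicate 1 (0.0886) or Hevin replicate 1 (0.163), with total counts only (0.0538), under the stricter cell filter (0.0756) and with called doublets kept (0.0696). Kif23 lost it without mCherry replicate 1 (0.0607) and by DESeq2 (0.0507), and Sall3 under the stricter filter (0.0604).

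The remaining lists did not pass in border-associated-macrophage-like cells. Camera adjusted p-values were 0.288 for developmental and disease-associated genes, 0.531 for NF-kappa-B genes, 0.752 for Toll-like receptor signalling, 0.440 for phagocytosis and complement, 0.938 for lysosome, 0.129 for S-phase genes, 0.449 for dissociation-induced genes, 0.542 for glycolysis, 0.804 for lipid handling, 0.211 for TGF-beta signalling and 0.225 for extracellular matrix. They were 0.165 for border-associated macrophage, 0.174 for monocyte, 0.574 for B cell, 0.403 for astrocyte, 0.299 for oligodendrocyte, 0.711 for neuron, 0.222 for endothelial and 0.542 for mural markers.

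The Hevin effect differed between the 2 classes for 63 of 15460 genes by a test of the interaction, all 63 with a smaller rise or a larger fall in border-associated-macrophage-like than in microglia-like cells. The named genes are expressed by macrophages of the brain borders or by activated myeloid cells. The difference of log2 fold changes was −2.78 ± 0.23 for Ms4a7 (edgeR adjusted p = 0.00024), −2.68 ± 0.27 for the inhibitory lectin receptor gene Clec12a (0.0013), −2.48 ± 0.34 for Ms4a4a (0.0067), −2.42 ± 0.25 for Cybb, the catalytic subunit of the phagocyte NADPH oxidase (0.0013), and −2.12 ± 0.28 for the aryl hydrocarbon receptor gene Ahr (0.0052). Ms4a7 had a log2 fold change of 2.89 in microglia-like and of 0.09 in border-associated-macrophage-like cells, and Clec12a of 3.58 and 0.83. In the mCherry libraries Ms4a7 stood at 13.9 and 8.45 plain CPM in microglia-like and at 716 and 700.1 plain CPM in border-associated-macrophage-like cells, and Clec12a at 2.17 and 1.18 against 53.8 and 60.1. With such baselines an equal gain in CPM gives a smaller log2 fold change in border-associated-macrophage-like cells. Leaving out 1 library raised the count, to 135 without mCherry replicate 1, 170 without mCherry replicate 2, 236 without Hevin replicate 1 and 116 without Hevin replicate 2, and a minimum of 10 CPM lowered it to 37.

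In endothelial-like cells, which are not myeloid, 23 of 11297 genes passed, 15 higher and 8 lower. Gpr65 (3.77 ± 0.49), Clec12a (3.40 ± 0.35), Ms4a7 (2.69 ± 0.23), Arhgap15 (2.61 ± 0.28) and Cybb (2.59 ± 0.24) were higher, and Csmd3 (−1.90), Slc2a5 (−1.66), Ccl9 (−1.57), Sall1 (−1.38) and Crybb1 (−1.30) were lower. Apoe was also higher (2.04, edgeR adjusted p = 0.0075). The 10 genes before it lost their call without mCherry replicate 1, at adjusted p-values from 0.0654 for Ms4a7 to 0.259 for Csmd3, where 4 genes passed in all. There were 16 genes without mCherry replicate 2, 50 without Hevin replicate 1 and 43 without Hevin replicate 2. In astrocyte-like cells edgeR called 0 of 4255 genes, with 164 at an unadjusted p below 0.05, and DESeq2 called 1. Lhfp (2.03) and Elapor2 (2.59) came closest among higher genes (edgeR adjusted p = 0.162 for both), followed by Bst2 (1.84) and Unc5c (1.85), and Crybb1 (−1.34), Smap2 (−1.69), P2ry12 (−1.09), Nav3 (−1.38) and Selplg (−1.44) among lower ones. Crybb1, P2ry12, Nav3 and Selplg were also leading genes of microglia-like clusters, and carried-over RNA was not tested in astrocyte-like cells. Leaving out 1 library gave between 3 and 55 genes.

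The share of microglia-like cells in division, those with at least 2 UMIs of genes of the G2 and M phases after each cell was thinned to 1000 UMIs, was 1.01% and 0.927% in the mCherry libraries and 1.40% and 1.17% in the Hevin libraries. In endothelial-like cells it was 2.22% and 1.42% against 1.80% and 2.19%, close to or above those values, and median depths were 5402, 6194, 3554 and 5769 UMIs against 3268, 3958, 2074 and 3312 UMIs in microglia-like cells. The groups differed by 0.41 ± 0.13 on the log2 scale (edgeR test on numbers of cells, p = 0.093, exact permutation p = 0.333). Thinning left out 108 microglia-like cells of Hevin replicate 1 and 0 of the other libraries, and without thinning the shares were 3.24% and 3.16% against 3.28% and 3.54%. In border-associated-macrophage-like cells the thinned shares were 1.44% and 1.58% (19 and 14 cells) against 3.03% and 2.30% (30 and 17 cells). Without thinning they were 14.3% and 15.9% against 11.2% and 17.1%, which overlap. In the Apoe-high cells of the Hevin libraries the thinned shares were 1.72% and 2.02%. They were 11.4% and 12.5% in those of the mCherry libraries, which numbered 44 and 24.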

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

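The tests of explanations in this part were chosen after the results they bear on had been seen, and the interaction test was chosen before.

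The Hevin effect differed between border-associated-macrophage-like and microglia-like cells for 63 genes by the interaction test, which is what brought these genes here. The difference of log2 fold changes was −2.78 for Ms4a7, −2.68 for Clec12a, −2.48 for Ms4a4a, −2.42 for Cybb and −2.12 for Ahr. Ms4a7 and Clec12a had higher levels in border-associated-macrophage-like cells of the mCherry libraries, where an equal gain in CPM gives a smaller log2 fold change.

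At an unadjusted p below 0.05 and at least 10 mean CPM, 21 genes more than doubled in microglia-like cells of the Hevin libraries. The median ratio of their rise in CPM in endothelial-like cells to that in microglia-like cells was 1.01. In UMIs per cell it was 2.25. Free RNA at an equal amount per cell would give 1 in UMIs, and free RNA in proportion to the depth of a cell would give 1 in CPM. Which of these holds was not tested. Free RNA from the Apoe-high cells may therefore account for some of these rises, and the ratio does not decide it. Of the 5 genes above, Ms4a7 and Clec12a rose in endothelial-like cells almost as much as in microglia-like cells (log2 fold change 2.69 and 3.40), and Cybb rose by 2.59. Ms4a4a had no value in endothelial-like cells, and Ahr had a log2 fold change of 1.18 there against 2.21 in microglia-like cells. Under the same bounds on p and CPM, 438 genes rose in microglia-like cells and had a value in both classes. Over them the median ratio in CPM was 0.665, with 378 rising in both, and a rise within microglia-like cells stays open. The injected virus is a biological difference that the design names, and it is untested against free RNA.

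The Apoe-high clusters held 51.7% and 42.9% of the cells of the Hevin libraries and under 0.25% of those of the mCherry libraries. Barcodes admitted at a lower depth are argued against, since the lower of the Hevin shares was still 43.3% among cells with 3000 or more UMIs. Doublets of microglia-like and border-associated-macrophage-like cells are argued against too, for the cells of this set. The median level of 8 border-associated macrophage markers in the set was 3.11% of that in border-associated-macrophage-like cells, although Pf4 (41.2%), Stab1 (32.9%) and Mrc1 (18.8%) stood higher. The naming by these markers and the bound on Sall1 would leave many such doublets out of the set, so the value is no independent check. Newly arrived monocytes with Ccr2 (0.641% of the level in unnamed cluster 18) are argued against as their identity, while Sall1 (9.08% of the level in microglia-like cells) decides nothing, since the set was picked for low Sall1. Microglia, macrophages that entered from outside, the Hevin protein itself and any difference between the virus preparations or injections stay open, because the group and the preparation cannot be separated by 4 libraries.

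Of 18 homeostatic microglia genes, 14 were lower in border-associated-macrophage-like cells of the Hevin libraries. The list lost its call by camera with an estimated correlation (adjusted p = 0.682) and by fry (adjusted p = 0.155). Their median log2 fold change in endothelial-like cells was −0.76, close to the −0.85 in border-associated-macrophage-like cells. Free or carried-over RNA from microglia-like cells, which are a smaller share of the Hevin libraries, may therefore be the source. The median was −0.70 with the top 5% of doublet scores removed, which does not decide on doublets, since the caller did not work in the mCherry libraries. The fall in CPM was 1.5 times as large as in endothelial-like cells (median ratio over 18 genes), and an effect of Hevin on the border-associated-macrophage-like cells themselves stays open as an untested addition.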

How the results depend on the processing

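The minimum of 3000 UMIs, the removal of the top 5% of doublet scores, the fits and shares with or without the Apoe-high clusters, the second clustering, all alternatives for the gene lists over all cells and all alternatives for endothelial-like and astrocyte-like cells were chosen after the data had been seen. The other alternatives were chosen before.

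With 1 library left out, the lone library is assumed to vary like the other group, and the ranges below give the lowest and highest of the 4 such fits. The Apoe-high share kept its direction and its call under every alternative that gave it a value (a class per cell leaves no unnamed cells), between 7.51 and 7.78 with 1 library left out, and at 3.46 in the second clustering, where the set was again picked by genes that differ between the groups. The share of dividing microglia-like cells and the shares of the microglia-like clusters passed under none. Numbers of genes stayed within 1.5 times their value under every alternative not named below. Reversals lie among classes with fewer than 75 cells in every library and among genes of other cell types within microglia-like cells, among others, and whether depth limits these values was not tested. Where no cause is named below, the cause was not tested.

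Numbers of genes past the threshold moved as follows. In microglia-like cells (0 genes by edgeR with 1068 at an unadjusted p below 0.05) there were 175 by DESeq2, 17 with a robust fit, 354 with no filter on low counts, 15 with a minimum of 10 CPM, which tests fewer genes, and 16 with called doublets kept. There were 48 at resolution 0.5, 39 with thinned cells, 2372 with a class per cell and 2280 with the Apoe-high clusters added, which brings their cells into the sums. Leaving out 1 library gave 10 to 116. The count stayed 0 with DESeq2's size factors, total counts, either other cell filter, 3000 UMIs, the top 5% of doublet scores removed, and without cycling clusters or ribosomal and mitochondrial genes. Over all cells (2110) there were 1314 with 3000 UMIs and 154 without the Apoe-high clusters, and 1371 to 2660 with 1 library left out. In border-associated-macrophage-like cells (138) there were 86 by DESeq2, 400 with no filter on low counts, 74 with the stricter cell filter, 36 with the top 5% of doublet scores removed and 42 with thinned cells, and 71 to 235 with 1 library left out. Leaving out 1 library gave 4 to 50 in endothelial-like cells (23) and 3 to 55 in astrocyte-like cells (0 by edgeR with 164 at an unadjusted p below 0.05), where DESeq2 called 1. For the interaction (63) it gave 116 to 236, and a minimum of 10 CPM gave 37.

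Shares of cell classes past the threshold (2) numbered 1 with 3000 UMIs, 0 by edgeR with a class per cell, which leaves no unnamed cells, and 1 to 2 with 1 library left out, where without mCherry replicate 2 the erythroid-like share passed and the microglia-like share did not. They numbered 3 with the stricter cell filter, at resolution 0.5 and in both second clusterings. Outside the Apoe-high clusters edgeR called 0, with 1 at an unadjusted p below 0.05 (fibroblast-like cells), and no exact permutation p was below 0.333. The log2 fold change of the microglia-like share was −1.31 with 3000 UMIs, 0.0059 with a class per cell, −0.14 outside the Apoe-high clusters, where the largest Hevin set is left out of the total, and −1.25 to −0.89 with 1 library left out. For classes without a call it reversed in several fits. Neutrophil-like cells had −0.26 to 1.00 with 1 library left out. Astrocyte-like cells had −0.97 to 0.017, and 0.0047 with the stricter cell filter. Oligodendrocyte-like cells had −1.32 to 0.45, and 0.15 with no cell filter, 0.24 with the stricter one and 0.14 at resolution 0.5. Oligodendrocyte-precursor-like cells had −0.40 to 0.25, and 0.57 with the stricter cell filter and 0.24 with a class per cell. Endothelial-like cells had 0.070 with 3000 UMIs. Outside the Apoe-high clusters, where the total is smaller, the values were 0.42 for border-associated-macrophage-like, 0.53 for astrocyte-like, 0.85 for oligodendrocyte-like, 0.94 for oligodendrocyte-precursor-like and 0.62 for endothelial-like cells.

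Lists past camera numbered 10 in microglia-like cells, 9 in border-associated-macrophage-like cells and 11 over all cells. With an estimated correlation they numbered 0 in each, and by fry 0, 0 and 2. The 2 were the interferon-response list (fry adjusted p = 0.0066) and the developmental and disease-associated list (0.0089). Leaving out 1 library gave 5 to 15, 5 to 11 and 10 to 14.

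The log2 fold change of Sparcl1 with 1 library left out was −0.43 to −0.022 over all cells, −0.68 to 0.86 in microglia-like cells and −0.21 to 0.69 in astrocyte-like cells. Over all cells the sign also reversed for Ddx3y (−0.079 to 1.24) and Xist (−9.22 to 0.71), the second with the sex of the libraries. With total counts it reversed for Tlr4 in all cells (−0.020).

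In microglia-like cells, named genes without a call reversed with 1 library left out, among them Abcc9 (−0.92 to 0.40), Aldoc (−1.20 to 0.66), C1ql1 (−1.58 to 1.73), Ccr2 (−0.28 to 0.52), Cd79b (−0.14 to 0.082), Col1a1 (−1.05 to 0.98), Col3a1 (−0.28 to 0.70) and Cxcl10 (−0.40 to 0.63). Further reversals were in Dcn (−1.14 to 1.43), Ddx3y (−0.29 to 1.05), Ebf1 (−0.44 to 0.26), F13a1 (−0.49 to 0.14), Gpr17 (−1.35 to 0.88), Ighm (−0.033 to 0.080), Itm2a (−0.98 to 0.18), Lyve1 (−0.54 to 0.22), Mal (−0.76 to 0.19), and Mbp (−0.74 to 0.27). The others were Rbfox3 (−0.45 to 0.29), Rgs5 (−0.90 to 0.63), Slc1a2 (−1.05 to 0.86), Slc1a3 (−0.45 to 0.055), Slco1a4 (−0.79 to 0.032), Syt1 (−0.13 to 0.24), Tafa2 (−5.16 to 0.41), Tagln (−1.67 to 0.23), Tlr4 (−0.016 to 0.16) and Xist (−9.14 to 0.67). Cxcl10 also had −0.41 with the stricter cell filter and Ighm −0.030 with total counts. Over all 216 values of named genes, the alternatives gave 1837 that kept direction and side of the threshold, 183 that gained a call, 47 that lost one and 52 that reversed.

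The libraries share replicate numbers, which nothing in the labels ties to a litter, batch or day, so the numbers were not taken as pairs. Deviations of libraries with the same number from their group means correlated at 0.612 in microglia-like cells, 0.607 over all cells and 0.310 in border-associated-macrophage-like cells. Replicate 1 of both groups also held the male cells, so the block takes in sex, and its part in these counts was not tested. With the replicate number as a block there were 646 genes in microglia-like cells, 4522 over all cells, 373 in border-associated-macrophage-like cells, 235 in endothelial-like cells and 3 in astrocyte-like cells, and 4 class shares, those of border-associated-macrophage-like and erythroid-like cells being added. Under the block Sparcl1 over all cells had −0.23 with a call, and the oligodendrocyte-precursor-like share 0.017. Under the block 12 lists passed camera in microglia-like cells, 11 in border-associated-macrophage-like cells and 10 over all cells, where the Toll-like receptor list did not pass (adjusted p = 0.0544, camera).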

Other observations

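The list values over all cells and in endothelial-like cells and the values of Tafa2 were chosen after the data had been seen, the other tests before, and no explanation was tested.

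Interferon-response genes led an Apoe-high cluster of 433 cells (Cxcl10, Ifit3 and Isg15). The median log2 fold change of this list was 1.12 over all cells, 0.61 in microglia-like cells, 0.21 in border-associated-macrophage-like cells and 0.24 in endothelial-like cells (16 genes). The G2 and M phase list had another order, with a median of 0.53 over all cells, 0.36 in microglia-like cells, 0.87 in border-associated-macrophage-like cells and 0.06 in endothelial-like cells. Differences between cell classes in these medians were not tested.

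Tafa2, which encodes a secreted brain peptide, stood at 67.6 CPM over all kept cells of mCherry replicate 1 and at 1.71, 2.23 and 1.51 CPM in mCherry replicate 2, Hevin replicate 1 and Hevin replicate 2. Its level in mCherry replicate 1 was alike in microglia-like (67.4 CPM), border-associated-macrophage-like (66.9 CPM) and endothelial-like cells (67.8 CPM).

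Other ways of splitting the same 4 libraries into pairs called 0 genes over all cells and in border-associated-macrophage-like cells. With edgeR, mCherry replicate 2 and Hevin replicate 2 against the rest gave 0 genes over all cells (1020 at an unadjusted p below 0.05), 0 in border-associated-macrophage-like cells (722) and 3 in microglia-like cells (2179). The split that put mCherry replicate 2 with Hevin replicate 1 gave 0 in each (75, 163 and 67). The groups themselves gave 2110, 138 and 0. There are 3 such splits, too few to weigh chance.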
